A study of Homo sapiens with 4 samples.

How the data were processed

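RNA from ARPE-19 cells was measured on 4 one-colour (Cy3) Agilent arrays, 1 for each of the groups named in the labels: control siRNA, PNPLA6 siRNA, mock vector and PNPLA6 vector. Per the labels, cells were harvested 72 hours after lipid transfection, total RNA came from 4 pooled wells per group, and 200 ng were amplified and labelled with a low-input kit. Each array's scanner table gives a background-subtracted and spatially detrended intensity for every spot, per the file headers, made with Agilent Feature Extraction 12.1.1.1 per the submitters' processing notes. The same tables hold the raw mean and local background intensity of each spot, per the file headers. The deposited value table holds a linear ratio, which was close to the processed signal divided by a constant for each array when the columns were set against the scanner values over 44495 spots. The ratio spanned less than 0.00005% on each of 3 arrays but 0.984% on the PNPLA6 vector array, for a reason that stayed unknown. Its median was 1408 for the control siRNA, 1129 for the PNPLA6 siRNA, 1139 for the mock vector and 1010 for the PNPLA6 vector, close to the 75th percentile of each array's signal. The medians of the deposited columns were 0.0871, 0.0848, 0.0802 and 0.0847 in the same order. All 4 arrays lay on 1 slide, so the place on the slide cannot be told apart from the group.

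Values were the log2 of the processed signal minus the 75th percentile of the array over its gene probes. Control spots were left out, and so were spots marked as uneven or as outliers within their probe (355, 310, 317 and 411 on the 4 arrays in the order above). Spots of a probe were averaged, 999 probes having 10 spots each and the rest 1. A probe counted as measured where it was well above background, which held for 70.0%, 65.6%, 67.3% and 65.2% of the 34127 probes, and no probe was saturated. A gene was represented by its measured probe with the highest mean signal, and text says where probes of a named gene differed in direction. Of the probes, 27349 were named by matching their transcript accession to a RefSeq gene table, 2487 by a gene name or synonym in it, and 4291 kept the name in the array files. That table describes a later assembly than the hg19 positions in the array files, and none of its coordinates were used. The probes of POR, LAT2 and IFI27 were designed on Ensembl transcripts. The table of all genes, and the figure drawn from it, omit XIST and genes with a copy on the Y chromosome. The median standard deviation of repeated spots was 0.07, 0.07, 0.09 and 0.11 (log2), and the number of arrays limits the precision of every comparison.

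Comparisons were PNPLA6 siRNA minus control siRNA, PNPLA6 vector minus mock vector and mock vector minus control siRNA. With 1 array per group no test was run, and genes were counted at a 2-fold difference. A gene not well above background on one array of a pair was given as a bound, its signal on the brighter array over the higher of its own signal and the lowest well-measured signal on the dimmer one. The design, the lists and 10 alternatives of processing with 2 alternative thresholds were chosen before the data were examined. For a gene list, the median difference was placed among 10000 random lists of the same size drawn from 20 bins of mean signal, as a description of these arrays. That percentile ignores that genes of a pathway vary together, so more lists than expected can stand outside the central 95%. There were 37 lists, 30 of pathways and 7 of cell type markers, and those with at least 5 measured genes were summarised.

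The 30 pathway lists were choline and CDP-choline pathway, ethanolamine and serine phospholipid synthesis, phospholipases and lysophospholipid acyltransferases, sterol biosynthesis, fatty acid synthesis and desaturation, triglyceride and lipid droplet, fatty acid oxidation, oxidative phosphorylation, mitochondrial biogenesis and dynamics, and glycolysis. They went on with G1/S and DNA replication, G2/M and mitosis, p53 targets, endoplasmic reticulum stress, amino acid response and ATF4 targets, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, antigen presentation, NRF2 targets and oxidative stress, and lysosome and autophagy. The last were RPE markers, epithelial-mesenchymal transition, extracellular matrix, heat shock proteins, hypoxia targets, one-carbon and methionine metabolism, replication-dependent histones, immediate early genes, senescence and growth arrest, and reference genes. Cell type markers covered photoreceptors, neurons, glia, immune cells, endothelial cells, keratinocytes and fibroblasts.

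Genes were named by a fixed rule. It took PNPLA6, the 10 highest and 10 lowest genes of a comparison with a gene symbol, a brighter array at or above the median signal and all measured probes differing in one direction, the 2 to 4 members of a list with the largest differences, genes 2-fold different in both comparisons under the same filters, and the 3 largest bounds per direction. The alternatives chosen beforehand were normexp background correction of the raw intensities (offset 50), quantile normalization, median centring, removal of a lowess trend (span 0.3), the deposited table, 3 other filters on dim genes, the median over a gene's probes, and outlier spots kept. Thresholds of 1.5-fold and 3-fold were tried too. Another 2 alternatives were chosen after the data had been seen, namely scaling on 9 E1A spike-in probes and leaving out the outer 5 columns of spots on either side. The width of 5 columns was chosen after the columns of the lowest knockdown genes had been looked at. A measure of the distance between spots of outlying genes and a local median correction were also tried at that point, and their values are not given.

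The steps were tested on simulated data with 200 genes of known difference among the 16737 genes of the knockdown and the 16545 of the overexpression. In both, 100% of genes set 4-fold higher passed the 2-fold threshold and 0% of unchanged genes did. Of genes set 2-fold higher, 48% passed in the knockdown and 52% in the overexpression, and of those set 2-fold lower, 48% and 62%. At 1.5-fold, 4% and 0% passed. Every simulated gene was given the same noise whatever its signal. These shares therefore do not give the rate of false 2-fold genes on the real arrays, least of all among dim genes. Among lists without a shift 4.5% lay outside the central 95% in the knockdown and 2.5% in the overexpression, and among lists shifted by 0.15 on the log2 scale 93.5% and 94.5% lay above it. Recovery of shifted lists ranged with the random seed, and its pass limit was lowered once a limit set too high for the number of lists drawn had been missed. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 for normexp. Levels of XIST and of genes with a copy on the Y chromosome were left out.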

Results

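Gene expression was measured in ARPE-19, a human retinal pigment epithelium (RPE) cell line, on 4 one-colour Agilent arrays. The groups were a negative control siRNA, an siRNA against PNPLA6, a mock expression vector and a vector carrying PNPLA6, with 1 array per group. Cells were harvested 72 hours after transfection, and each array received RNA combined from 4 wells. There were therefore no replicates, no difference between groups could be set against the spread between cultures, and every value describes these 4 arrays. Each array held 34127 gene probes under 25608 gene names. Of these probes, 23874 were well above background with the control siRNA, 22381 with the PNPLA6 siRNA, 22973 with the mock vector and 22243 with the PNPLA6 vector. The spread of repeated spots within an array gave a technical standard deviation of 0.10 (log2) for a difference between the 2 siRNA arrays. It was 0.14 between the 2 vector arrays and 0.12 between the 2 control arrays. This spread covers spots on an array and not cultures, pooling or labelling.

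PNPLA6 encodes neuropathy target esterase, a lysophospholipase of the endoplasmic reticulum that acts on phosphatidylcholine and lysophosphatidylcholine. It was read by 1 probe, A_23_P16166, designed on transcript NM_006702 from its base 3916. The probe lies on chromosome 19 from 7625582 to 7625641 (hg19) and has the sequence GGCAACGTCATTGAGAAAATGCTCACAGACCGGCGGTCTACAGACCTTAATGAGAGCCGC. The processed signal of PNPLA6 was 428 with the control siRNA, 151 with the PNPLA6 siRNA, 309 with the mock vector and 4997 with the PNPLA6 vector, well above background on all 4 arrays. Relative to the 75th percentile of each array, the PNPLA6 level was -1.72, -2.90, -1.88 and 2.31 (log2) in the same order. PNPLA6 was thus 2.27-fold lower with its siRNA than with the control siRNA, at 44.1% of the control level (log2 difference -1.18, technical standard deviation 0.11). That standard deviation comes from other, repeated probes of like signal, since the PNPLA6 probe has 1 spot per array. PNPLA6 ranked 48 from the lowest of the 16737 genes measured on both siRNA arrays. It was 18.2-fold higher with its vector than with the mock vector (log2 difference 4.19), the highest of the 16545 genes measured in that comparison. Between the 2 control arrays PNPLA6 differed by -0.16 (mock vector minus control siRNA). Which part of the transcript the vector carried is not given in the sources used here.

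**Figure D1:**
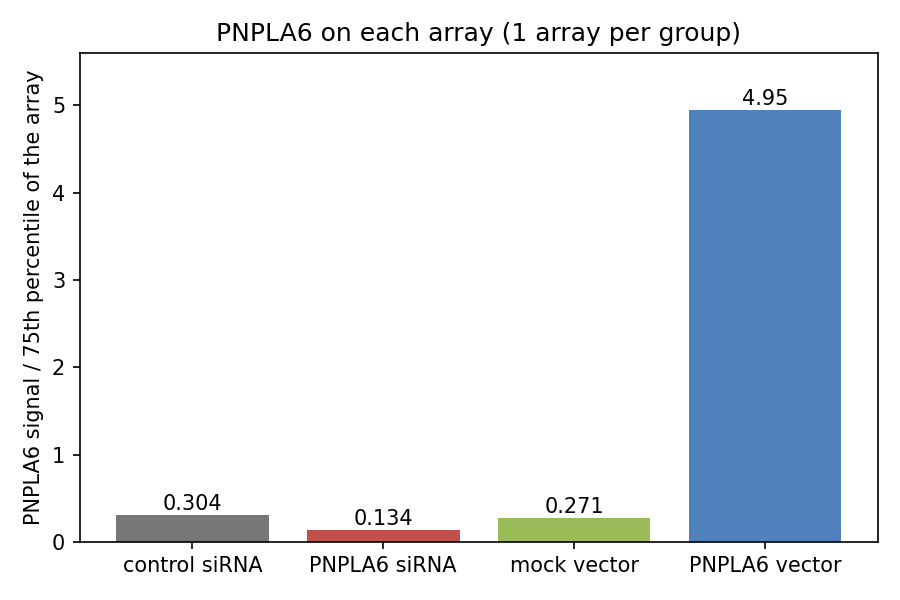
PNPLA6 signal divided by the 75th percentile of the array (vertical axis, linear, no unit) on each of the 4 arrays, 1 bar per array. The level was 0.304 with the control siRNA, 0.134 with the PNPLA6 siRNA, 0.271 with the mock vector and 4.95 with the PNPLA6 vector.

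The first comparison, PNPLA6 siRNA against control siRNA, asks which transcripts differ where PNPLA6 is silenced. Few genes differed by much. CLDN4, a claudin of tight junctions, was higher with the PNPLA6 siRNA by 1.00 on the log2 scale. Genes of the amino acid response were higher together by small amounts, none of 31 reaching 1.5-fold, with CHAC1, which degrades glutathione, at 1.49-fold and PCK2, mitochondrial phosphoenolpyruvate carboxykinase, at 1.41-fold. Spike-in scaling, which takes 1 constant off every gene, made the median of this list negative, but the list stayed above its random lists under all 12 alternatives. It was also higher with the mock vector than with the control siRNA. IGFBP7, a secreted protein that binds insulin-like growth factors, was 1.87-fold lower. Relative to the control siRNA, IGFBP7 was also 1.66-fold lower with the mock vector and 2.45-fold lower with the PNPLA6 vector. The control siRNA array thus had the highest level of this gene, and its difference was not particular to the PNPLA6 siRNA.

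Of 16737 genes measured on both siRNA arrays, 53 were at least 2-fold higher and 75 at least 2-fold lower with the PNPLA6 siRNA, so that 41.4% of these differences were upward. With arrays scaled on their E1A spike-in probes the upward share was 17.1%, since that scaling moved the median difference of all genes from 0.03 to -0.24 and every gene with it. Among the genes whose brighter array was at or above the median signal, 2 were higher and 9 lower at 2-fold. Of these brighter genes the highest were POR, cytochrome P450 reductase (log2 difference 1.04), CLDN4 (1.00), CRCP, a subunit of RNA polymerase III (0.73), the ribosomal RNA gene RNA5-8SN5 (0.72) and the hair keratin genes KRT31 (0.62) and KRT33B (0.58). The small nucleolar RNA gene SNORA71A (0.56), GGTLC3 (0.55), a member of a family of close copies, KRT34 (0.53) and TTC38 (0.51) followed, and the probes of the near-identical keratins cannot be fully told apart. POR was also 1.09 higher with the mock vector than with the control siRNA, and its probe was designed on an Ensembl transcript. The lowest were MPLKIP, mutated in a form of trichothiodystrophy (-1.31), EVI5L, which carries a Rab GTPase-activating domain (-1.29), CST5, a cysteine protease inhibitor (-1.23), DMXL1, a partner of the vacuolar proton pump (-1.12), and LAT2, an adaptor of immune receptors (-1.11). They were followed by the translation initiation factor EIF2A (-0.92), IGFBP7 (-0.90), ANKRD36BP2 (-0.89), ARGLU1, a modulator of splicing (-0.85), and BIN1, which bends membranes (-0.85).

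Most of the genes that were lower with the PNPLA6 siRNA were also lower on both vector arrays. Of 57 such genes measured on all 4 arrays, 46 (80.7%) were at least 1.5-fold lower on both vector arrays than on the control siRNA array, while in 4 the PNPLA6 siRNA array was at least 1.5-fold lower than both vector arrays. Both counts share an array with the selection of the genes. They would be equal only if noise on the 2 siRNA arrays were equal and as often downward as upward. On the control siRNA array alone, 26 genes were at least 2-fold above the other 3 arrays and 2 below. On the PNPLA6 siRNA array alone, these counts were 14 and 1. Of 27 genes higher with the PNPLA6 siRNA, 7 were at least 1.5-fold higher on both vector arrays than on the control siRNA array, and in 19 the PNPLA6 siRNA array was that far above both vector arrays. In both directions the siRNA array with the higher signal was thus more often the one apart. Among the lower genes DMXL1, for example, was -1.44 with the mock vector relative to the control siRNA, CST5 -1.32 and EVI5L -1.21. Of the 75 genes, 23 (30.7%) had their spot in the outer 5 of 85 columns on either side of the array, against 11% of all measured genes, a width chosen after the columns of the lowest of these genes had been seen. The spots of 7 of the 10 lowest genes named above (MPLKIP, EVI5L, DMXL1, LAT2, IGFBP7, ANKRD36BP2 and ARGLU1) and of 5 of the 10 highest (POR, CLDN4, CRCP, RNA5-8SN5 and TTC38) lay in these columns, as did those of 8 (15.1%) of all 53 higher genes. With those columns left out, an alternative chosen after the positions had been seen, 45 genes were higher and 53 lower.

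Genes near or below background on one array are given as bounds. HOXB13 was at least 14.3-fold higher with the PNPLA6 siRNA, RDH8, a retinol dehydrogenase of photoreceptors, at least 13.7-fold and GRM5, a glutamate receptor, at least 8.92-fold. SIRPB2 was at least 10.1-fold lower, FABP7, a fatty acid binding protein, at least 9.71-fold and the olfactory receptor gene OR6N2 at least 8.36-fold. SIRPB2 and FABP7 were likewise at least 10.5-fold and 10.1-fold lower with the mock vector than with the control siRNA.

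The lipid pathways closest to the enzyme differed little with the PNPLA6 siRNA. All 23 measured genes of the choline and CDP-choline pathway lay within 1.5-fold (median 0.02), the largest differences being those of the choline transporter-like gene SLC44A5 (-0.39) and the phosphodiesterase GDE1 (-0.33). All 15 genes of ethanolamine and serine phospholipid synthesis (median 0.06) and all 26 phospholipases and lysophospholipid acyltransferases (median 0.08) lay within 1.5-fold too, with ETNK2, an ethanolamine kinase, at 0.27 and PLA2G4A, a cytosolic phospholipase, at -0.34. So did all 23 genes of sterol biosynthesis (median 0.01), all 21 of fatty acid synthesis and desaturation (median -0.02; the desaturase SCD 0.42) and all 20 of triglyceride and lipid droplet metabolism (median 0.06; GPAM, an acyltransferase, 0.33). In fatty acid oxidation 26 of 27 genes lay within 1.5-fold (median 0.04), and the regulator PPARGC1A was -0.72, but -0.04 by its other probe. Of the phospholipases, PLB1 was -0.43, its probes differing in direction. None of these 7 medians lay outside the central 95% of 10000 random lists of the same size and signal.

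Of 35 gene lists with at least 5 measured members, 3 lay outside that range, against 1.75 expected of unrelated lists. The amino acid response and ATF4 target list had a median of 0.14 (percentile 99.98), with 28 of 31 genes above 0 and none at 1.5-fold, and its median was -0.12 with spike-in scaling. NRF2 targets and oxidative stress genes had a median of 0.14 (percentile 98.7, 20 of 23 genes above 0), led by OSGIN1 (0.94) and the cystine transporter SLC7A11 (0.39), and a median of -0.13 with spike-in scaling. This list was inside the range under 5 of 12 alternatives, quantile normalization (0.02) and removal of a lowess trend (0.03) among them. Replication-dependent histones had a median of 0.11 (percentile 98.4, 21 of 26 genes above 0), with H3C4 at 0.37 and the linker histone H1-4 at -0.61, and a median of -0.15 with spike-in scaling. Histone genes are close copies of each other, so the single members are uncertain. Spike-in scaling adds 1 constant to every difference, so that the 3 lists kept their distance from the median of all genes.

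The medians of the other lists lay inside the range. They were 0.12 for epithelial-mesenchymal transition (percentile 96.9), 0.10 for immediate early genes (percentile 95.6), 0.10 for extracellular matrix (percentile 90.4), 0.09 for p53 targets, where the cell cycle inhibitor CDKN1A was 0.36, and -0.02 for interferon-stimulated genes. COL5A1, a fibrillar collagen of the matrix list, was 4.02-fold higher by 1 dim probe, at -4.35 with the control siRNA and -2.34 with the PNPLA6 siRNA. The median was 0.02 for G1/S and DNA replication, 0.02 for G2/M and mitosis, 0.13 for glycolysis, 0.11 for oxidative phosphorylation and 0.03 for mitochondrial biogenesis and dynamics. It was 0.06 for endoplasmic reticulum stress, 0.05 for inflammatory cytokines and NF-kB targets (the chemokine CXCL6 0.68), 0.08 for antigen presentation, 0.02 for lysosome and autophagy, and 0.05 for RPE markers, where the phagocytosis receptor MERTK was 0.69 and the melanosome enzyme TYRP1 -0.50. Heat shock proteins had a median of 0.06, hypoxia targets 0.07, one-carbon and methionine metabolism 0.04, senescence and growth arrest 0.06 and reference genes 0.13. Markers of other cell types gave medians of 0.09 (photoreceptor), 0.10 (neuron), 0.11 (immune cell), 0.04 (keratinocyte) and 0.03 (fibroblast). Markers of glia and endothelial cells had fewer than 5 genes measured in each comparison and were not summarised.

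The second comparison, PNPLA6 vector against mock vector, asks which transcripts differ where PNPLA6 is in excess. Beyond PNPLA6, genes of the extracellular matrix and epithelial-mesenchymal transition lists were higher with the PNPLA6 vector, among them the collagens COL1A1 (2.35-fold) and COL4A1 (2.20-fold), the myosin light chain MYL9 (2.17-fold) and the actin-binding calponin CNN1 (2.07-fold). Relative to the control siRNA, however, both lists were lower with the mock vector (medians -0.72 and -0.63) and, by less, with the PNPLA6 vector (-0.20 and -0.36). Interferon-stimulated genes were also higher with the PNPLA6 vector than with the mock vector, with the antiviral RSAD2 at 2.43-fold and CMPK2 at 2.06-fold. Genes of DNA replication and mitosis were lower by smaller amounts, such as the licensing factor CDT1 (-0.61, log2) and the phosphatase CDC25C (-0.59), but these lists were higher with the mock vector than with the control siRNA. Replication-dependent histones were lower, with H1-4 at 2.08-fold and H2BC5 at 1.93-fold, single members being uncertain.

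Of 16545 genes measured on both vector arrays, 172 were at least 2-fold higher and 60 at least 2-fold lower with the PNPLA6 vector. The upward share was 74.1%, against 61.2% with each array centred on its median and 86.9% with spike-in scaling. Among the brighter genes, 38 were higher and 13 lower. After PNPLA6 the highest were ANOS1, an extracellular matrix glycoprotein (1.99), PRUNE2 (1.99), MDGA1, a membrane-anchored adhesion protein (1.97), ADAMTS5, which cleaves aggrecan (1.94), ANXA8L1, an annexin with near-identical copies (1.47), and NPPB, which encodes brain natriuretic peptide (1.42). KCTD16, a subunit associated with GABA receptors (1.35), RSAD2 (1.28) and GASK1B (1.28) followed. Among the lowest were ARGLU1 (-1.86), the small nucleolar RNA gene SNORA62 (-1.51), IL13RA2, a decoy receptor of interleukin 13 (-1.35), PSMC3IP, which acts in meiotic recombination (-1.06), and H1-4 (-1.05). GRK2, a kinase of G protein-coupled receptors (-1.05), CDC42EP5, an effector of CDC42 (-1.03), CCM2L (-1.02) and CEP15, a centrosomal protein (-1.02), were also among them. Of the genes named here, ADAMTS5, GASK1B, ARGLU1, H1-4 and CEP15 had their spots in the outer columns of the array. As bounds, HMSD was at least 11.7-fold, TBC1D3JP at least 8.94-fold and FAM225A at least 8.82-fold higher, while WDFY4 was at least 14.2-fold, MAB21L3 at least 8.15-fold and KRT73-AS1 at least 7.74-fold lower.

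Many genes that were higher with the PNPLA6 vector were low on the mock array relative to the control siRNA array. Of 152 such genes measured on all 4 arrays, 86 (56.6%) were at least 2-fold lower with the mock vector than with the control siRNA, and in 75 of them the PNPLA6 vector lay between the 2 control arrays. In 33 of the 152 the PNPLA6 vector was at least 2-fold above the control siRNA. Both counts share an array with the selection of the genes. PRUNE2, for instance, stood at 1.59 with the control siRNA, -2.44 with the mock vector and -0.45 with the PNPLA6 vector (log2 relative to the 75th percentile). IL13RA2 took the opposite course, at -4.17, -0.36 and -1.71.

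Of 34 lists (neuron markers having too few genes measured), 18 lay outside the central 95% of their random lists, against 1.7 expected of unrelated lists. The extracellular matrix list had a median of 0.38 (100th percentile), and 10 of 27 genes were at least 1.5-fold higher and none lower, with the microfibril gene FBN1 at 0.91. Of the epithelial-mesenchymal transition list (median 0.21, percentile 99.99), 8 of 25 genes were at least 1.5-fold higher, including the growth factor-like CCN2 (0.90) and the actin-binding TAGLN (0.89). Fibroblast markers had a median of 0.49 over 6 genes (percentile 99.95), with FAP, a membrane protease, at 0.75 and the growth factor receptor PDGFRB at 0.60; 4 of the 12 genes of this list also belong to the matrix list. Senescence and growth arrest genes had a median of 0.15 (percentile 99.0), with IGFBP5 at 0.69 and IGFBP3 at 0.65. These 4 lists had medians below 0 with the mock vector relative to the control siRNA (-0.72 for matrix, -0.63 for epithelial-mesenchymal transition, -0.28 for fibroblast markers and -0.42 for senescence).

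Interferon-stimulated genes had a median of 0.42 (100th percentile), with 35 of 37 genes above 0 and 6 at least 1.5-fold higher, including ISG20 (0.97), a nuclease, and SAMD9L (0.93). Inflammatory cytokines and NF-kB targets had a median of 0.26 (percentile 99.8; 0.20 and inside the range with the brighter genes only), and the cytokines IL1B (1.16), CXCL1 (0.83) and IL6 (0.80) were higher while TNFAIP2 was -0.67. Hypoxia targets had a median of 0.31 (100th percentile), with the carbonic anhydrase CA9 at 0.86 and the angiogenic factor VEGFA at 0.65. Of the RPE markers (median 0.18, percentile 99.8, but 0.11 and inside the range with the brighter genes only), 7 of 25 genes were at least 1.5-fold higher, among them the water channel AQP1 (0.94, its probes differing in direction), the retinol acyltransferase LRAT (0.93) and the melanin enzymes TYRP1 (0.91) and DCT (0.73). On the mock array TYRP1 (-6.18) and LRAT (-5.75) were near the lowest well-measured signal (-6.29). Glycolysis (0.09, percentile 98.7; the aldolase ALDOC 0.88 and the glucose transporter SLC2A3 0.60) and endoplasmic reticulum stress (0.11, percentile 99.3; the chaperone HSP90B1 0.53) lay above their ranges, inside them under 2 and 1 of 12 alternatives. Lysosome and autophagy genes stood at the edge with a median of 0.07 (percentile 97.51) that was inside the range under 3 of 12 alternatives and -0.01 with median centring.

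Replication-dependent histones had the lowest median, -0.45 (percentile 0), with 26 of 27 genes below 0 and 8 at least 1.5-fold lower, H4C8 (-0.89) and H3C7 (-0.75) among them. The G1/S and DNA replication list had a median of -0.24 (percentile 0, 27 of 31 genes below 0), with the replication factor MCM10 at -0.58. The G2/M and mitosis list had a median of -0.21 (percentile 0, 30 of 33 genes below 0), with the kinase AURKA at -0.38. Oxidative phosphorylation had a median of -0.11 (percentile 0.47, 43 of 49 genes below 0), with the respiratory complex subunits NDUFA9 at -0.65 and NDUFA6 at -0.61. One-carbon and methionine metabolism (-0.18, percentile 0.26; SHMT2 -0.39, CTH -0.36) and heat shock proteins (-0.16, percentile 1.19; HSPA6 -0.72, its probes differing in direction) were below their ranges, the latter inside it under 2 of 12 alternatives. The amino acid response list had a median of -0.14 (percentile 0.665, but 2.94 and inside the range, at the same median, with the brighter genes only), with the amino acid transporter SLC1A5 at -0.82 and asparagine synthetase, ASNS, at -0.75 (its probes differing in direction) but the stress cytokine GDF15 at 0.64. The signs of these 7 medians were the same under median centring and spike-in scaling. With the PNPLA6 vector relative to the control siRNA, G1/S (0.11, percentile 89.4), G2/M (0.11, percentile 88.3), oxidative phosphorylation (0.15, percentile 94.0) and one-carbon metabolism (0.09, percentile 69.4) were inside their ranges, whereas all 4 were above them with the mock vector relative to the control siRNA.

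The lipid lists again lay inside their ranges. Medians were 0.01 for the choline and CDP-choline pathway, -0.06 for ethanolamine and serine phospholipid synthesis, 0.11 for phospholipases and lysophospholipid acyltransferases (percentile 97.2), 0.04 for sterol biosynthesis, 0.01 for fatty acid synthesis and 0.00 for both triglyceride metabolism and fatty acid oxidation. SLC44A5 was 3.52-fold higher with the PNPLA6 vector and ETNK2 1.59-fold, while the phospholipase PLD1 was -0.58. PNPLA7, the closest relative of PNPLA6, was 1.55-fold higher by its brighter probe but 0.03 (log2) by its other one. The phospholipase gene PLB1 was 2.01-fold higher, its probes differing in direction. SLC44A5 had been 5.50-fold lower with the mock vector than with the control siRNA. TP63, a transcription factor of basal epithelia, was 3.46-fold higher, and the median of keratinocyte markers was 0.13 over 6 genes. The mock signal of TP63 (-6.09, log2) was close to the lowest well-measured signal on that array (-6.29), so its fold is uncertain.

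**Figure D2:**
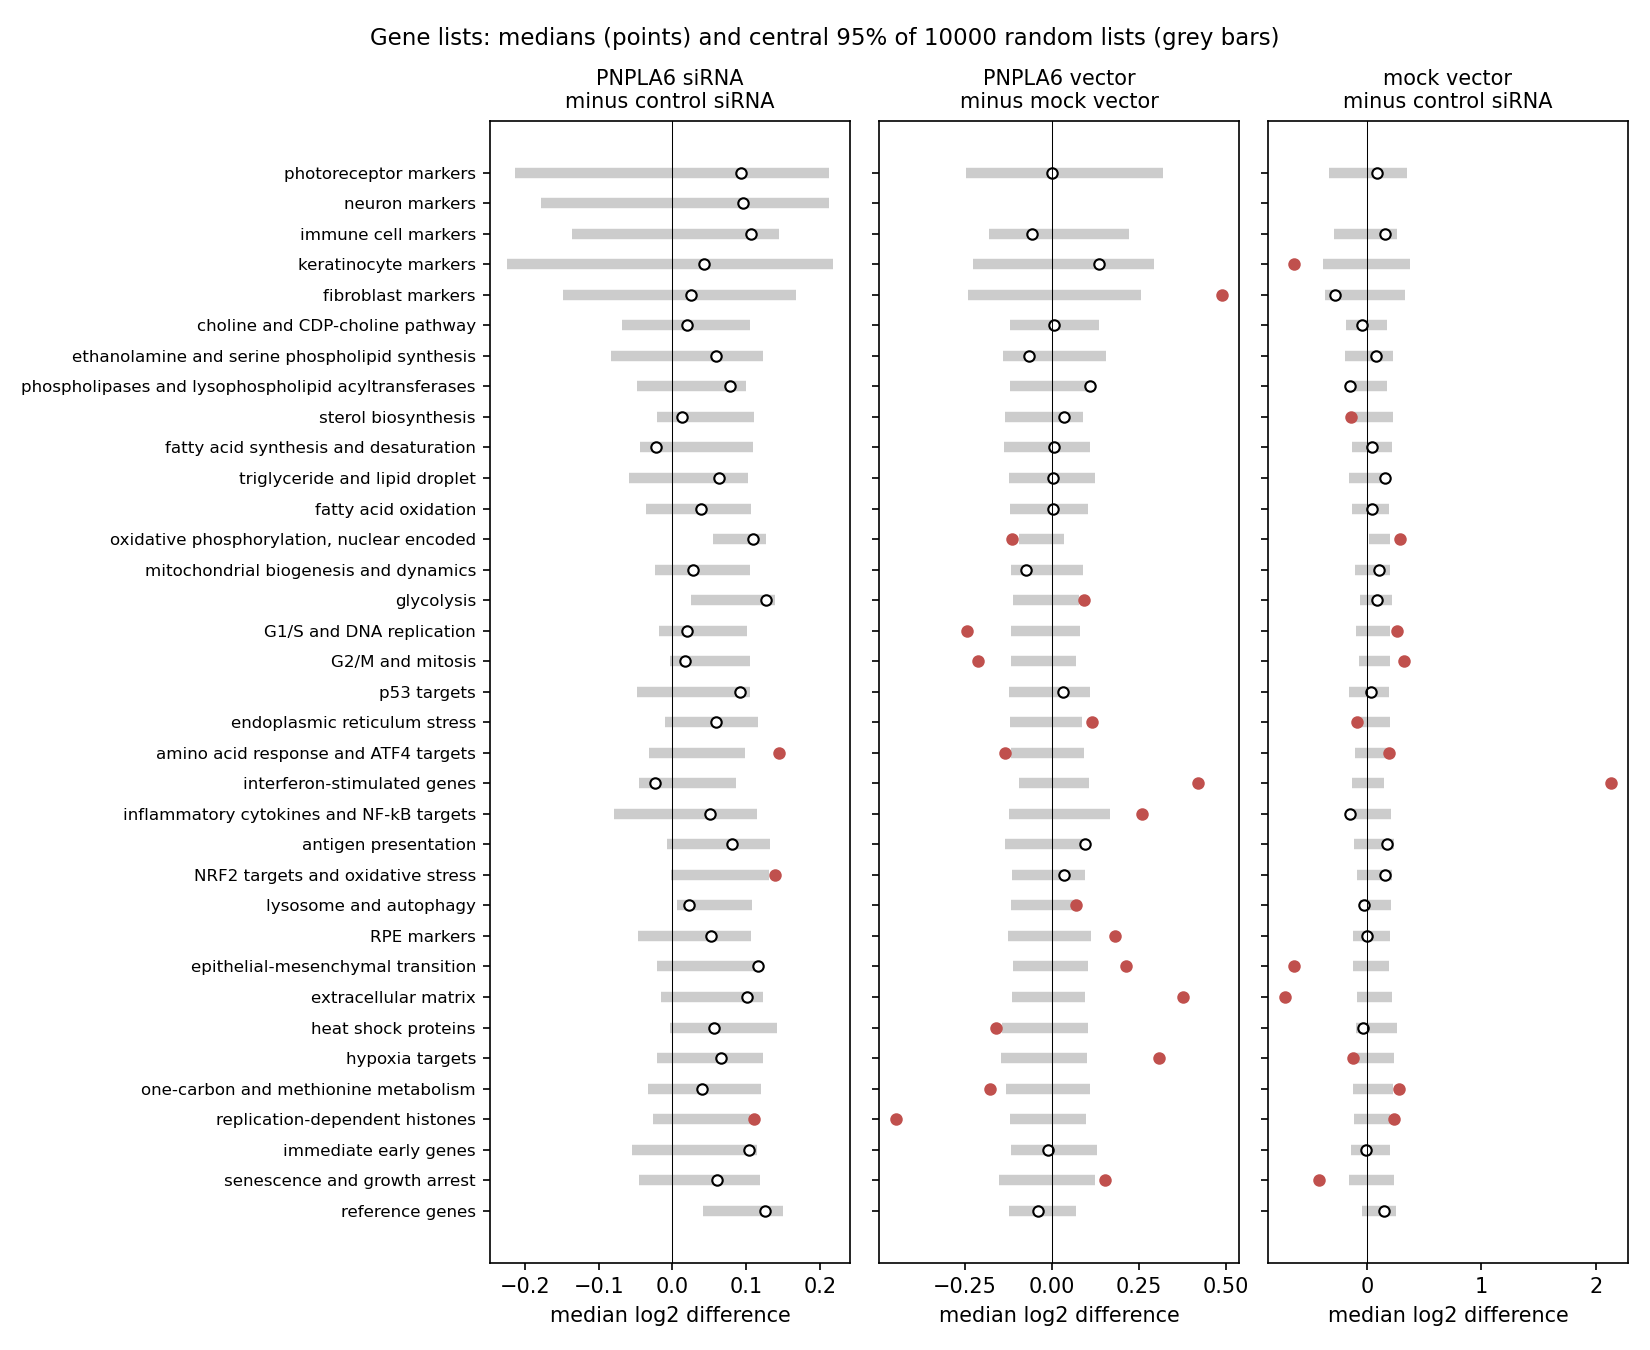
Median log2 difference of each gene list (horizontal axis) in the 3 comparisons, 1 point per list, filled where it lies outside the central 95% of 10000 random lists of the same size and signal (grey bars); the horizontal scales differ between panels. With the PNPLA6 siRNA 3 of 35 medians lay outside, against 18 of 34 with the PNPLA6 vector and 14 of 34 between the controls. The 3 turn negative with spike-in scaling, which takes 1 constant off every gene and keeps their distance from the median of all genes. The lysosome median with the vector and the endoplasmic reticulum stress median between the controls change sign with median centring, likewise a constant.

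The 2 control arrays differed at 2-fold in 619 genes, against 128 with the PNPLA6 siRNA and 232 with the PNPLA6 vector. Interferon-stimulated genes were far higher with the mock vector than with the control siRNA. The difference was 112-fold for IFITM1, which restricts viral entry, 63.3-fold for OAS1, a sensor of double-stranded RNA, and 53-fold for IFI6. It was 41.3-fold for OAS2 by its brighter probe (2.61, log2, by its other one) and 37.1-fold for IFI44L. CMPK2 (23.9-fold), BST2, which tethers virions (21.8-fold), IFI27 (19.4-fold), the ubiquitin-like ISG15 (18.5-fold) and IFIT1 (16.2-fold) followed. Of 34 measured interferon-stimulated genes 28 were at least 2-fold higher and none lower (median 2.13, 100th percentile). OASL and RSAD2, not well above background with the control siRNA, were at least 35.0-fold and 31.5-fold higher.

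Genes of the extracellular matrix and epithelial-mesenchymal transition lists were lower with the mock vector. Of all brighter genes, PRUNE2 (16.3-fold), ANOS1 (10.4-fold), ADAMTS5 (9.83-fold), COL1A1 (8.56-fold) and AMTN, an enamel matrix protein (7.83-fold), were lowest, followed by the natriuretic peptide receptor NPR3 (6.75-fold), ANGPTL7 (5.73-fold), MDGA1 (5.50-fold), MYL9 (5.22-fold) and EDIL3, an integrin ligand (5.20-fold). SFRP4, a secreted Wnt modulator, was at least 17.6-fold lower. Of the matrix list 14 of 27 genes were at least 1.5-fold lower and none higher (median -0.72), and of the epithelial-mesenchymal transition list 13 of 25 were lower and 1 higher (median -0.63). Senescence and growth arrest genes had a median of -0.42, with IGFBP5 at -1.78, and a median of -0.071, inside the range, with normexp background correction. Keratinocyte markers had a median of -0.63 over 5 genes, inside the range under 2 of 11 alternatives and 0.14 with no filter on background. Sterol biosynthesis (-0.14), hypoxia targets (-0.12, VEGFA -1.46) and endoplasmic reticulum stress (-0.08, but 0.02 with median centring) were below their ranges by less, hypoxia targets inside under 5 of 12 alternatives and endoplasmic reticulum stress under 7.

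Lists higher with the mock vector were oxidative phosphorylation (median 0.29, 41 of 49 genes above 0), G2/M and mitosis (0.32, 31 of 33), G1/S and DNA replication (0.27, 30 of 31), one-carbon and methionine metabolism (0.28, inside the range under 1 of 12 alternatives), replication-dependent histones (0.24) and the amino acid response list (0.20, percentile 97.97, inside under 3). CDT1 was 0.97, the kinesin KIF2C 0.64, the cyclin CCNB1 0.59 and the serine synthesis enzyme PSAT1 0.92. Of 17051 genes measured on both control arrays, 203 were at least 2-fold higher and 416 lower with the mock vector, an upward share of 32.8% that was 45.1% with median centring, which moved the median difference of all genes from 0.04 to 0.14. This comparison shares an array with each of the other 2, and differences in the kind of nucleic acid and in the vector itself cannot be separated in it.

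**Figure D3:**
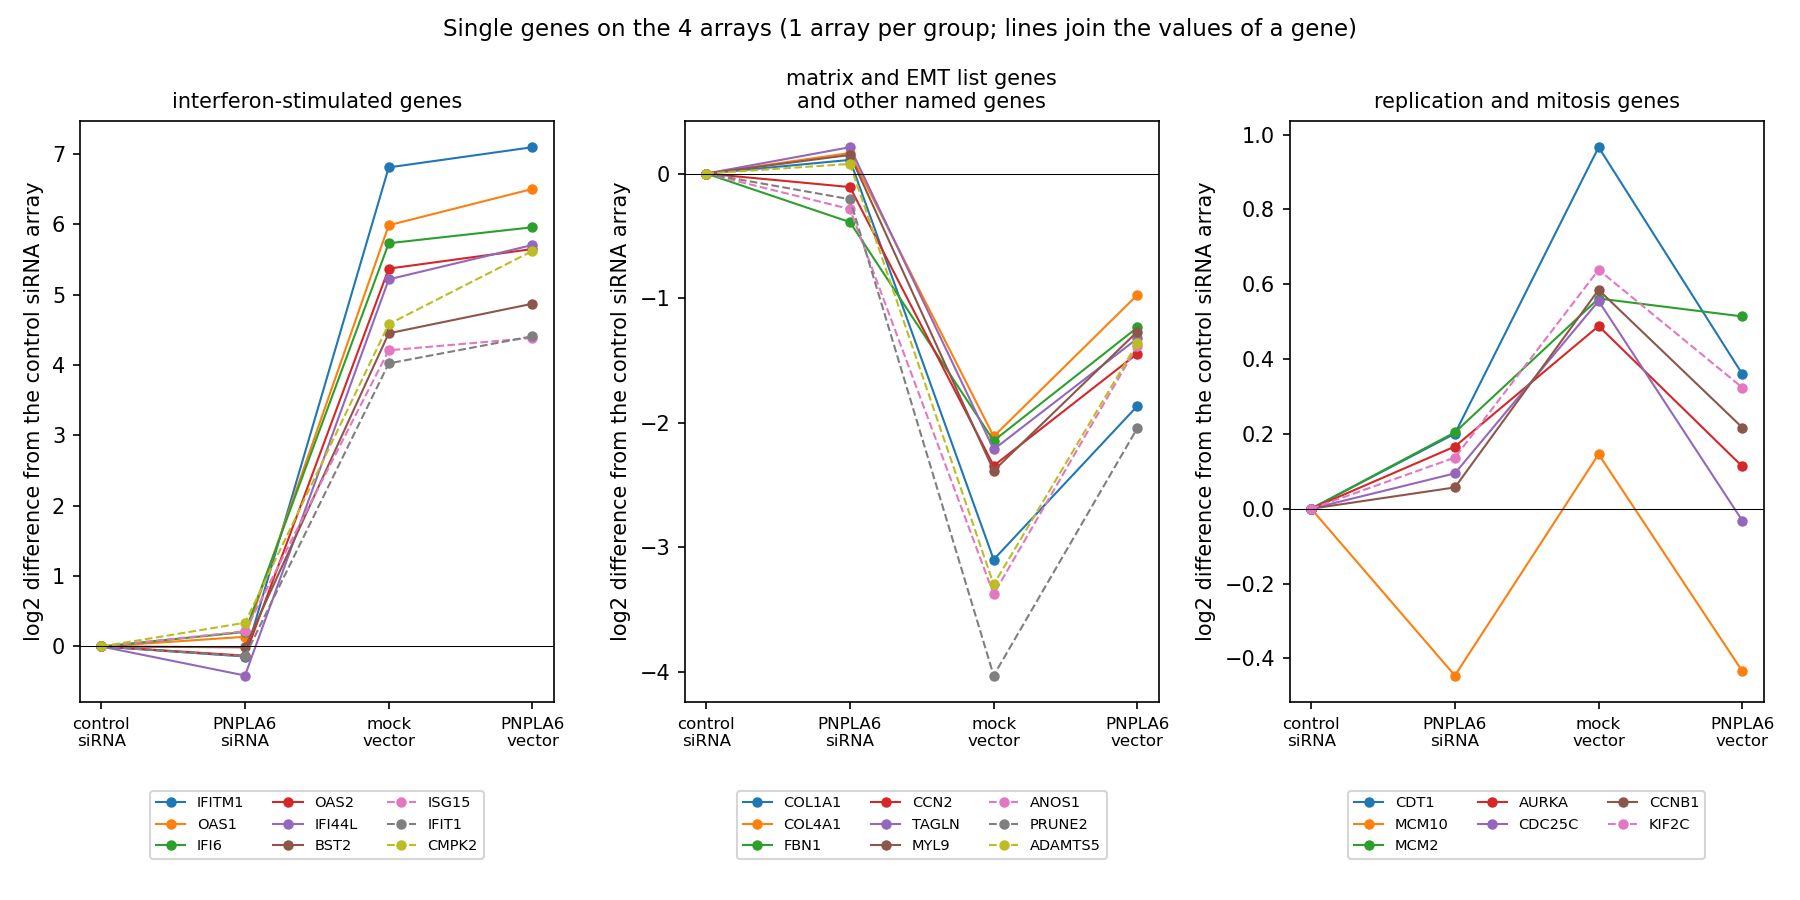
Log2 difference of single genes from the control siRNA array (vertical axis) on the 4 arrays (horizontal axis), with lines joining the values of a gene (EMT, epithelial-mesenchymal transition). IFITM1 was 6.81 higher and COL1A1 -3.10 with the mock vector relative to the control siRNA, and COL1A1 was 1.23 higher with the PNPLA6 vector than with the mock vector.

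The knockdown and the overexpression share no array. Across 16185 genes measured on all arrays their differences had a Pearson correlation of -0.05 and a Spearman correlation of -0.07, genes not being independent replicates. At 2-fold, 3 genes were lower with the PNPLA6 siRNA and higher with the PNPLA6 vector, against 0.539 expected of independent lists, and no gene was higher with the siRNA and lower with the vector. They were PNPLA6 itself, which the siRNA and the vector targeted, RTN4RL1 and TEKT4P2. Another 3 were lower in both, against 0.169 expected, the only one with a gene symbol being CLEC1B. They were named after their values had been seen, since 0 genes passed the filters for naming. The expected numbers treat dim and bright genes alike. At 1.5-fold the overlap was above the expected number in every direction. It was 22 against 8.67 (lower with the siRNA, higher with the vector), 7 against 2.46 (the reverse), 9 against 5.24 (higher in both) and 16 against 4.07 (lower in both). In 54.7% of the genes both vector arrays lay on one side of both siRNA arrays, where 33.3% would be found by chance. In 20.1% both PNPLA6-targeted arrays lay on one side of both controls. In 25.1% the remaining pairing held, that of PNPLA6 vector and control siRNA, in which the knockdown and the overexpression differ in opposite directions. Both of these shares were below the 33.3% found by chance for each pairing.

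**Figure D4:**
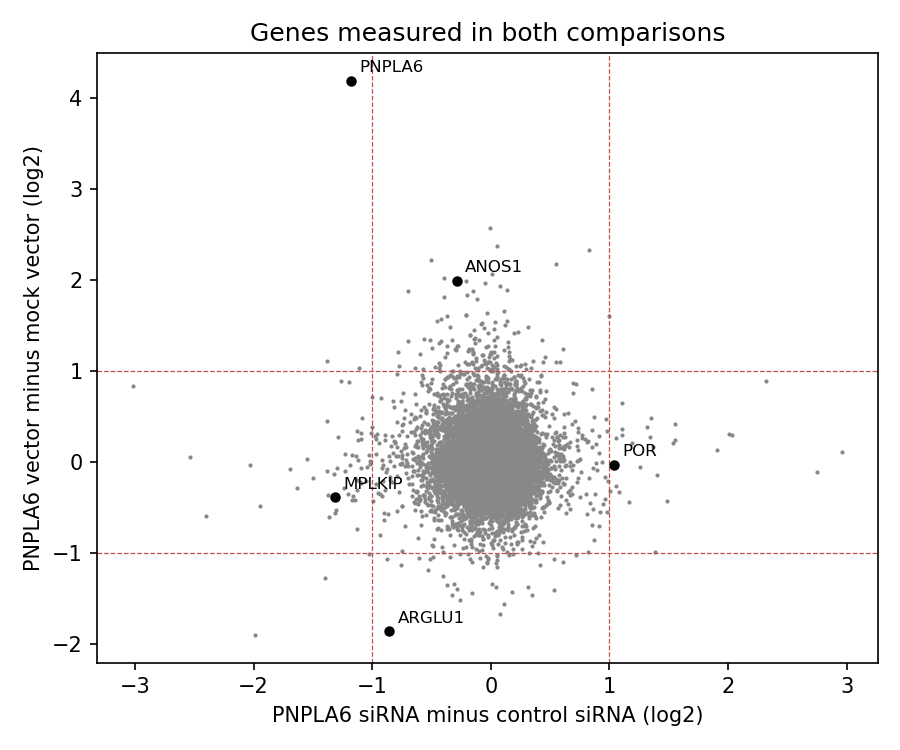
Log2 difference of each gene with the PNPLA6 siRNA against the control siRNA (horizontal axis) and with the PNPLA6 vector against the mock vector (vertical axis), 1 point per gene, with dashed lines at 2-fold. PNPLA6 lies at -1.18 and 4.19, and the correlation across genes was -0.05.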

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

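Of the tests below, those of an intensity trend were chosen before their results were seen, and all the others after.

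The amino acid response and ATF4 target list stood above its random lists with the PNPLA6 siRNA and below them with the PNPLA6 vector, a difference of medians of 0.28 that was not tested against any spread between cultures. An intensity trend between arrays is argued against, since the median with the siRNA was 0.11 (percentile 99.99) and with the vector -0.12 (percentile 1.12) once a lowess trend was removed. A tendency of these genes to vary together between any 2 arrays stays open and is consistent with their median of 0.20 (percentile 97.97) between the 2 controls, where PNPLA6 was not targeted; that value was inside the central 95% under 3 of 12 alternatives. A list set by the PNPLA6 level alone is argued against, as far as the control siRNA array is not itself low for these genes. The median was 0.16 (percentile 99.13, inside the central 95% under 2 of 12 alternatives) with the PNPLA6 vector relative to the control siRNA. The list was thus higher as in the knockdown although PNPLA6 was far higher. The knockdown uses the same control siRNA array. Relative to it the median was 0.14 with the PNPLA6 siRNA, 0.20 with the mock vector and 0.16 with the PNPLA6 vector. The value below the range with the PNPLA6 vector relative to the mock vector was inside it with the brighter genes only (percentile 2.94), at an unchanged median of -0.14. A response to PNPLA6 on top of a difference between vectors and siRNAs stays open, untested without replicates.

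The replication-dependent histones also stood apart in opposite directions, under all 12 alternatives, with a difference of medians of 0.56 that was not tested. Unlike the amino acid list, they were lower with the PNPLA6 vector relative to the control siRNA (median -0.31, percentile 0). A list that falls as PNPLA6 rises stays open for them, and no check of it was set. Their median was also 0.24 (percentile 99.4) with the mock vector relative to the control siRNA, where PNPLA6 differed by -0.16. Control probes that no comparison uses also held signal, 9 E1A spike-in probes being well above background on all 4 arrays, and their median difference relative to the 75th percentile was 0.23 with the PNPLA6 siRNA (single probes -0.11 to 0.35), -0.12 with the PNPLA6 vector (-0.25 to 0.11) and 0.06 between the controls (-0.42 to 0.21). The scaling on these probes took the middle probe level of each array, and so took off a constant of 0.27, -0.10 and 0.01 in the same order.

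Genes at least 2-fold lower with the PNPLA6 siRNA could reflect the control siRNA array more than the siRNA. In 80.7% of those measured on all 4 arrays, both vector arrays were at least 1.5-fold lower than the control siRNA array as well (46 genes), whereas in 4 genes the PNPLA6 siRNA array was that far below both vector arrays. A high signal on the control siRNA array may therefore account for most of them, whether from that array or from a difference shared by the other 3. Uneven signal near the side edges of an array stays open, since the 30.7% of the genes with a spot in the outer columns cannot decide it, the width of these columns having been chosen after the columns of the lowest of the genes were seen. A course that follows the PNPLA6 level in both directions, with a rise of at least 2-fold, is argued against for most of the genes. Of 57 measured on both vector arrays, 3 were at least 2-fold higher with the PNPLA6 vector than with the mock vector, PNPLA6 itself counted among both. The median was -0.059 (quartiles -0.35 and 0.14). The bound used, an upper quartile below a 2-fold rise, was set after the result was seen. Only 172 of all 16545 genes rose that far. Most sets of genes would therefore meet this bound, and it does not decide on smaller rises. It replaced a first one, a median below the central 95% of random sets, that was not met (percentile 6.42). Relative to the control siRNA the median was -1.15 with the mock vector, where PNPLA6 differed by -0.16, and -1.20 with the PNPLA6 vector.

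The extracellular matrix list was higher with the PNPLA6 vector than with the mock vector, and lower on both vector arrays than on the control siRNA array. Smaller uptake of vector DNA with the PNPLA6 vector is argued against as far as interferon-stimulated genes follow the amount of DNA, since their list was higher with that vector too (median 0.42, 100th percentile). A mock array that stands apart stays open, under a bound rewritten after the result was seen; the first one, any median of the PNPLA6 vector relative to the control siRNA outside the central 95%, was met and had argued against it. Relative to the control siRNA the matrix median was -0.72 with the mock vector and -0.20 (percentile 0.01) with the PNPLA6 vector, so the mock array lay further off without being the only one, and 82 genes were at least 2-fold below the other 3 on the mock array alone. The value of -0.20 argues against a list set by the PNPLA6 level alone, PNPLA6 being far higher with that vector. A response to PNPLA6 in both directions on top of a difference between vectors and siRNAs stays open, as the median with the PNPLA6 siRNA was 0.10 (percentile 90.4), inside the central 95%. The culture, the vector batch and the place on the slide, each held by 1 array, cannot be told apart from the group.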

How the results depend on the processing

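The spike-in scaling and the outer columns left out were chosen after the results were seen, the other alternatives before. Values were counted as close where a count was within 1.5 times the reported one, the correlation within 0.1, a list median within 1 standard deviation of its random lists, and a gene within the technical standard deviation. Of 129 values of counts, PNPLA6 and correlation under the alternatives 97 stayed close to those reported and 32 moved; of 1222 list medians 987 stayed close, 229 moved and 6, of lists outside their ranges, changed sign, as did 106 of lists inside; of 703 values of named genes 635 stayed close and 68 moved. What is limited here is signal over background: most 2-fold genes were dim (91.4% of those of the knockdown). The correlation ran from -0.073 to 0.015, the latter with normexp. With normexp, PNPLA6 was -0.96 in the knockdown and 3.93 in the overexpression, and the counts of higher and lower genes were 9 and 16 in the knockdown and 46 and 13 in the overexpression, with 300 genes different between the controls. With no filter on background the counts were 498 and 711, 758 and 711, and 1977, more genes being counted. With the brighter genes only they were 2 and 9, 38 and 13, and 232, fewer genes being counted; PNPLA6 in the knockdown is below this filter and has no value. With genes well above background on all 4 arrays, 27 were higher in the knockdown. At 1.5-fold the counts were 174 and 248, 708 and 335, and 2297, and at 3-fold 15 and 18, 29 and 5, and 183. With spike-in scaling PNPLA6 was -1.45 in the knockdown, 31 genes were higher and 150 lower there, 35 were lower in the overexpression, and the knockdown medians were -0.12 for the amino acid response, -0.13 for NRF2 targets and -0.15 for histones, since 1 constant is added to each difference. With median centring, likewise a constant, the overexpression median of the lysosome list was -0.0072 and the controls' endoplasmic reticulum stress median 0.019. With no filter the controls' keratinocyte median was 0.14, for which the cause was not tested, as with the normexp values. Leaving out the outer columns gave 45 and 53, 153 and 52, and 558. No paired analysis was possible because each group has 1 array.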

Other observations

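Of the tests below, that of an intensity trend was chosen before its result was seen, and the others after.

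Genes of antigen presentation were higher with the PNPLA6 vector than with the control siRNA. Their median was 0.28 (percentile 99.98, 19 genes measured), with the immunoproteasome gene PSMB9 at 1.65 and the peptide transporter TAP1 at 1.07. PSMB9 (1.43) and TAP1 (1.03) were likewise higher with the mock vector than with the control siRNA, so these differences were not particular to the PNPLA6 vector. With the mock vector relative to the control siRNA the median was 0.18 (percentile 87.78), and with the PNPLA6 vector relative to the mock vector 0.09 (percentile 96.9), both inside the central 95%. With the PNPLA6 vector relative to the control siRNA, interferon-stimulated genes had a median of 2.62, hypoxia targets 0.24 (percentile 99.92), glycolysis 0.19 (percentile 97.66) and the amino acid response list 0.16 (percentile 99.13), while epithelial-mesenchymal transition (-0.36), extracellular matrix (-0.20), replication-dependent histones (-0.31) and senescence genes (-0.18) were lower.

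Single list members with large differences between the 2 controls included the aldo-keto reductase AKR1B10, 3.85-fold higher with the mock vector, the transcription factor EGR2, 3.07-fold higher, and the complement gene C3, 3.62-fold lower. The water channel AQP1 was 6.47-fold lower by its brighter probe but -0.18 (log2) by its other one. IVL, a protein of the cornified envelope, was 6.45-fold lower. Its mock signal (-5.97, log2) was close to the lowest well-measured signal on that array (-6.29), so its fold is uncertain. Of 16185 genes measured on all arrays, 82 were at least 2-fold below the other 3 on the mock array alone, against 2, 1 and 7 on the control siRNA, PNPLA6 siRNA and PNPLA6 vector arrays. At least 2-fold above the other 3 were 17 genes on the mock array alone, against 26, 14 and 31.

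One hypothesis was that the lower G2/M and mitosis list with the PNPLA6 vector may come from the mock array alone. Its median with the PNPLA6 vector relative to the control siRNA was 0.11 (percentile 88.3), inside the central 95%, which is consistent with a mock array that stands apart for these genes. An intensity trend is argued against, since the median was -0.17 (percentile 0) with the PNPLA6 vector relative to the mock vector once a lowess trend was removed.

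Small nuclear, nucleolar and ribosomal RNA genes appear among the named genes, and a second hypothesis was that these classes may differ more between arrays than other genes of like signal. Their median absolute difference stood above the range of random lists with the PNPLA6 vector (0.31, percentile 99.97, 47 genes) and between the controls (0.47, 100th percentile, 48 genes). With the PNPLA6 siRNA it was 0.16 (percentile 92.6, 46 genes), so the hypothesis, which asked for all 3 comparisons, stays open.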
